A study of Mus musculus with 40 samples.

How the data were processed

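Oocytes of 5 follicle stages were measured on 2 Affymetrix array types, 430A and 430B, with 4 biological replicates per stage and array type and 40 samples in all. Per the labels' protocols, RNA was purified with a column kit made for small samples, amplified by the manufacturer's small-sample procedure and labelled with biotin. Per the submitters' processing notes the values come from MAS5, and no version or scaling target is given in the sources used here. The deposited values are array signals, a linear intensity per probe set, with no detection calls used here. Trimmed means of the deposited arrays lay between 151.1 and 154.5 on 430A and between 144.4 and 147.6 on 430B, so the arrays had been brought to a common level before deposit. Median deposited signals lay between 42.6 and 55.5 on 430A and between 58.2 and 84.8 on 430B. The number of arrays limits the precision, and low signals have no counting error that can be computed.

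Groups and replicate numbers were taken from the sample titles. For 3 small antral samples on 430B the extraction protocol names the age and oocyte number of the secondary stage; the group from the title was kept, and the comparisons were repeated without them. The labels call the replicates biological and do not say which animals each sample came from, so a p-value measures the spread between these samples.

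The columns of primordial replicates 2 to 4 held values on a grid of 0.05, with between 49.4% and 50.2% of values off the 0.1 grid, against 0% in the other stages and in primordial replicate 1 (controls and 100 further probe sets of 430A left out). Such a value times 2 minus replicate 1 was negative for 0 of 22526 probe sets on 430A and gave arrays with trimmed means of 147.8, 147.8 and 148 beside 147.8 for replicate 1 on 430A. Unmixed values were formed that way as an alternative chosen after the data were seen. For 100 probe sets of 430A, whose values lay off the grid at other stages too, no unmixed value was used. Doubled values of primordial replicate 3 fell below replicate 1 in 10 of these 100, and those of replicates 3 and 4 in 1 and 2 of the 64 control probe sets of 430A, so the form of a mean with replicate 1 is stated for the other probe sets. The 64 control probe sets had values in the 430A table for every stage but primary, and in the 430B table for primary alone. A planned check through probe sets measured on both array types in the same sample could therefore not be run, and control ratios were compared among the other stages.

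Each array was scaled to a 2% trimmed mean of 500, 32 was added and log2 was taken, so fold changes of low signals are understated. A probe set was tested where at least 4 of 20 arrays reached 100, whatever their stage, which kept 15845 on 430A and 19115 on 430B. The array types were fitted apart with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided), with all 20 arrays of a type in 1 fit, 15 residual degrees of freedom and no block. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 within its table. The 5 comparisons made were the 4 consecutive transitions and primordial to large antral. Tests of gene lists used limma's camera on 430A with 1 probe set per gene and a correlation preset at 0.01, adjusted over 135 tests of 27 lists and 5 comparisons. None of the 12 calls made so was kept with an estimated correlation, and that adjusted p is given beside each. The estimates for the called lists lay between -0.005 (egg surface, fertilization and activation) and 0.343 (cytoplasmic ribosomal proteins). The lost call of the egg surface list is therefore not explained by a higher correlation. Numbers of members that rose or fell include genes measured on 430B alone. The 27 lists, 22 of biology and 5 of other ovarian cell types, were fixed before the data were examined, as were the tests and the other alternatives.

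Genes were named by a rule of the same date. Among called probe sets with 1 symbol and no overlap of the 4 samples of each stage, it takes the 6 largest rises and 6 largest falls on 430A and 2 and 2 on 430B. It adds up to 4 members of each called list with the smallest adjusted p in its direction, and 18 fixed genes, of which 16 had a tested probe set with a single symbol. Npm2 and Ccnb1 are not reported. For genes highest in 1 stage it takes 5 per stage on 430A. A gene is represented by 1 probe set, with 430A before 430B. Symbols came from the platform annotation: on 430A 20380 of 22626 probe sets had 1 symbol, 691 several and 1555 none, and on 430B 14565 of 22411 had 1, 241 several and 7605 none. The reference gene table matched 20351 and 14390 of them by gene identifier and changed 0 symbols.

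The procedure was tested on simulated arrays, drawn independently around each probe set's mean over all stages with its residual SD. Changes were added to the simulated small antral arrays, and the secondary to small antral comparison was scored. Of 50 probe sets each, simulated log2 changes of 0.5, 1, 2 and 3 were recovered in 24%, 76%, 100% and 100% on 430A (15845 probe sets). On 430B (19115) they were recovered in 6%, 34%, 88% and 98%. False calls were 7 of 165 on 430A and 6 of 122 on 430B. The simulation had no array effects and no correlation between genes, so real changes may be recovered less well. It also held few changes: the real comparison called 2577 probe sets on 430A and 1063 on 430B. The adjusted threshold is stricter where fewer probe sets change, so on that account real changes may be recovered better. Alternatives were an offset of 0 or 64, signals as deposited, quantile normalization, scaling to the median, no filter or a minimum of 200, no variance trend, array weights, fits of the 2 stages alone, the replicate number as a block, each replicate left out, the mean of all probe sets of a gene for list tests, and the samples with the conflicting protocol left out. Fits without the primordial stage and with unmixed primordial values were added after the data were seen. Signal ratios of control probe sets were compared by exact permutation tests. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the remaining steps.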

Results

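The series measured transcript levels in mouse oocytes at 5 stages of follicle growth, in females of the SJLB6 background. Primordial follicle oocytes came from mice 2 days old, primary from mice 6 days old, secondary from mice 12 days old, small antral from mice 17 days old and large antral from mice 24 days old. A sample pooled 400 oocytes at the primordial stage, then 90, 60, 30 and 20 at the later stages. Mouse age and pool size changed with each stage, so differences between stages cannot be told apart from effects of either. RNA was amplified and hybridised to a pair of Affymetrix mouse array types, 430A and 430B, which carry different probe sets. Each stage had 4 biological replicates on each array type, so the series held 40 samples. The arrays reported relative levels within a fixed total, not transcripts per oocyte. After scaling, between 57.4% and 64.7% of 430A probe sets and between 65.8% and 77.9% of 430B probe sets reached a signal of 100. The median standard error of a log2 change was 0.17 on 430A and 0.34 on 430B, so the 430B arrays resolved smaller changes less well.

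The 4 deposited primordial samples were not independent of each other on either array type. Doubling the value of replicate 2, 3 or 4 and subtracting replicate 1 gave a negative result for 0 of 22526 probe sets on 430A and 0 of 22411 on 430B. This count leaves out 64 control probe sets and 100 others of 430A with values off the 0.1 grid at other stages, where up to 2 and 10 results were negative. In the 48 ordered pairs of replicates of the other stages the same operation gave between 1085 and 2814 negative results on 430A, and between 1972 and 3773 on 430B. Outside those probe sets these columns therefore had the form of means of replicate 1 with another array, and replicate 1 carried 62.5% of the weight of the deposited primordial mean. Replicate SDs at this stage were understated and p-values were too small. Changes of genes and lists from the primordial stage are accordingly given as deposited and from "unmixed" values, that is, 2 times the deposited value minus replicate 1 for replicates 2 to 4, an alternative chosen after the data were seen. The unmixed fit also shared 1 variance per probe set over all stages. Mean correlations with the other replicates were 0.891 to 0.931 for unmixed primordial 430A arrays, against 0.968 to 0.983 at other stages. On 430B they were 0.796 to 0.806, against 0.906 to 0.927. Standard errors and p-values of unmixed changes from the primordial stage may therefore still be too small.

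The primordial to primary transition compares oocytes before and after entry into growth, with mouse age and pool size also different. Obox2, Gdf9, Zp1 and Bub1b were among the transcripts that rose, and Selenop, Syce3, Figla and Sycp3 among those that fell. The largest rises on 430A included Cpa1, a carboxypeptidase, with a log2 change of 5.85 ± 0.21 (SE, n = 4 per stage; 5.56 ± 0.31 unmixed). Obox2, an oocyte homeobox gene, went from a scaled signal of 114.6 ± 22.6 (SD, n = 4) to 7718.4 ± 642 (log2 change 5.73 ± 0.11; 5.52 ± 0.15 unmixed). Rfpl4 rose by 5.30 ± 0.14 on the log2 scale (5.30 ± 0.24 unmixed), the growth factor gene Fgf8 by 4.64 ± 0.13 (4.55 ± 0.15 unmixed), Mos by 4.45 ± 0.13 (4.67 ± 0.26 unmixed) and Mfap2 by 4.34 ± 0.16 (4.03 ± 0.22 unmixed). On 430B, Gm1070 rose by 7.09 ± 0.13 (7.02 ± 0.15 unmixed) and Pabpn1l, a poly(A)-binding protein gene, by 5.97 ± 0.33 (5.49 ± 0.43 unmixed).

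Among the falls, Selenop, which encodes a secreted selenoprotein, had a log2 change of -4.13 ± 0.24 (-4.40 ± 0.27 unmixed), and Retreg1, an endoplasmic reticulum phagy receptor gene, of -3.47 ± 0.23 (-3.82 ± 0.28 unmixed). Hmmr changed by -3.31 ± 0.21 (-3.37 ± 0.22 unmixed), Bex3 by -3.33 ± 0.25 (-3.12 ± 0.28 unmixed) and Psat1, of serine synthesis, by -3.88 ± 0.27 (-3.15 ± 0.38 unmixed). Coq8a changed by -3.93 ± 0.37 as deposited and by -2.90 ± 0.50 unmixed. On 430B the synaptonemal complex gene Syce3 changed by -4.81 ± 0.30 (-4.30 ± 0.36 unmixed) and 2410006H16Rik by -4.31 ± 0.25 (-2.55 ± 0.63 unmixed). The adjusted p of these genes lay at or below 2.4e-09 as deposited and at or below 0.0041 unmixed. The 4 unmixed primordial signals of 2410006H16Rik were 3073.7, 261, 1593.7 and 67.5, a spread that the variance shared over stages may understate.

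Zona pellucida and oocyte-secreted factor genes rose together: 7 of 8 tested members rose and 0 fell, also 7 and 0 when adjusted over the list alone and with the unmixed values. The mean log2 change on 430A was 2.28 (2.04 unmixed; camera adjusted p = 1.5e-05, and 0.0011 unmixed). With an estimated correlation the adjusted p was 0.22. Gdf9, a growth factor that the oocyte sends to its granulosa cells, went from 5052.5 ± 889.5 to 26831 ± 1294.5, a log2 change of 2.42 ± 0.10 (2.20 unmixed). Bmp6 rose by 3.25 ± 0.10 (3.25 unmixed), Zp1 by 2.53 ± 0.10 (2.48 unmixed), Bmp15 by 2.30 ± 0.19 (1.85 unmixed) and Zp3 by 0.98 ± 0.10 (0.78 unmixed). Zp2 was already at 21678 ± 4994.6 in primordial oocytes and at 20424.6 ± 987.8 in primary oocytes, with a log2 change of -0.05 ± 0.12 (adjusted p = 0.73). From an unmixed primordial level of 29983 ± 10672.6 its change was -0.44 ± 0.19 (adjusted p = 0.062). Zp2 passed the threshold as a rise with quantile normalization (log2 change 0.295) and as a fall without primordial replicate 1 (-0.232).

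Of 24 maternal-effect genes, which act in the early embryo, 15 rose and 3 fell (15 and 4 adjusted over the list alone; 15 and 1 unmixed). Their mean change was 1.08 (1.09 unmixed; camera adjusted p = 0.0062, 0.0091 unmixed and 0.22 with an estimated correlation). The oocyte linker histone gene H1f8 rose by 4.17 ± 0.13 (4.89 unmixed), the imprint-protecting zinc finger gene Zfp57 by 3.47 ± 0.13 (3.59 unmixed), Dnmt3l by 2.24 ± 0.12 (2.25 unmixed), Btg4 by 2.19 ± 0.09 (2.01 unmixed), Zar1 by 2.18 ± 0.13 (1.81 unmixed) and the maintenance methyltransferase gene Dnmt1 by 1.74 ± 0.16 (1.28 unmixed). Nlrp5 had a log2 change of -0.02 ± 0.09 (adjusted p = 0.84; -0.24 ± 0.12 and 0.12 unmixed), but passed the threshold at 0.346 with quantile normalization. Among 33 genes of meiotic arrest and resumption 22 rose and 6 fell (22 and 6 adjusted over the list alone; 22 and 4 unmixed), with a mean change of 0.81 (1.02 unmixed). The camera adjusted p was 0.0062 (0.0038 unmixed), and the adjusted p with an estimated correlation was 0.25. The spindle checkpoint kinase gene Bub1b rose by 2.75 ± 0.10 (3.05 unmixed), Aurkc by 1.95 ± 0.13 (1.64 unmixed) and Map2k1 by 1.37 ± 0.08 (1.47 unmixed). Of 19 egg surface, fertilization and activation genes 14 rose and 3 fell (14 and 3 adjusted over the list alone; 13 and 3 unmixed). Their camera adjusted p was 0.0079 (0.035 unmixed), and 0.22 as the adjusted p with an estimated correlation. Oog4 rose by 3.84 ± 0.12 (3.66 unmixed), Astl, which encodes the protease that alters the zona after fertilization, by 2.78 ± 0.10 (2.99 unmixed) and Oas1c by 1.83 ± 0.08 (1.74 unmixed).

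Of 16 oocyte transcription factor genes 6 rose and 6 fell (6 and 6 adjusted over the list alone; 5 and 5 unmixed; camera adjusted p = 0.67). Sohlh1 went from 25186.1 ± 7468.1 to 3837.7 ± 284.5 on 430B, a log2 change of -2.67 ± 0.16, but its unmixed change was -1.45 (adjusted p = 0.004). Its 4 unmixed primordial signals were 36220.5, 5900.9, 10835.5 and 5240.7, so replicate 1 set much of the deposited level. Figla changed by -1.60 ± 0.13 (-1.10 unmixed) and Lhx8 by -0.50 ± 0.11 (-0.76 unmixed), while Nobox rose by 0.39 ± 0.12 (0.59 unmixed). Kit, the receptor of the granulosa cell ligand, had a log2 change of 0.07 ± 0.15 (adjusted p = 0.73), passed the threshold only unmixed (0.59, adjusted p = 0.039), and had another probe set that went the opposite way. Of 27 meiotic prophase genes 6 rose and 16 fell (7 and 16 adjusted over the list alone; 5 and 12 unmixed), and the list as a whole did not pass the threshold (camera adjusted p = 0.09, and 0.1 unmixed). The axial element gene Sycp3 went from 5907 ± 728.8 to 1167.4 ± 130.7 (log2 change -2.31 ± 0.16; -2.53 unmixed). The recombinase gene Dmc1 had a log2 change of -0.22 ± 0.23 (adjusted p = 0.44; -0.32 ± 0.28 and 0.37 unmixed).

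Cytoplasmic ribosomal protein and oxidative phosphorylation transcripts were higher in the deposited primordial values, and the size of this difference depended on the weight of replicate 1. Of 48 ribosomal protein genes 43 fell and 0 rose toward the primary stage (43 and 0 adjusted over the list alone), against 20 that fell and 1 that rose unmixed. Their mean change was -1.02 (camera adjusted p = 3.6e-13, and 0.32 as the adjusted p with an estimated correlation), or -0.32 unmixed (adjusted p = 0.0063). Against the separate unmixed primordial arrays the mean change to the primary stage was -1.30, 0.07, -0.59 and 0.54. In the same order, the unmixed log2 ratios of 3' to 5' signal of the Actb control were 1.77, 5.94, 3.03 and 6.24 and the unmixed 18S ribosomal RNA signals 4274.3, 13371.8, 7407 and 10406, for control probe sets that did not all follow the form of the others. An exact permutation test of the 4 unmixed against the 4 primary list means gave p = 0.4857. Rps28 changed by -1.67 ± 0.09 (-1.82 unmixed) and Rps20 by -1.54 ± 0.10 (-1.77 unmixed), whereas Rps3a1 changed by -2.22 ± 0.13 (-1.32 unmixed) and Rpsa by -1.97 ± 0.14 (-1.56 unmixed). Of 88 oxidative phosphorylation genes 55 fell and 8 rose (57 and 9 adjusted over the list alone; 35 and 14 unmixed). The mean change was -0.63 (camera adjusted p = 3.2e-09, and 0.3 as the adjusted p with an estimated correlation), or -0.23 unmixed (adjusted p = 0.0038), and -0.83, -0.03, -0.32 and 0.25 against the 4 unmixed arrays (exact permutation p = 0.3429). The 18S ribosomal RNA control had a deposited signal of 6569.6 in primordial samples, and its primary values are held with the other array type and cannot be compared. The complex I genes Ndufv2, Ndufa12, Ndufc1 and Ndufa1 changed by -2.03 ± 0.09, -2.20 ± 0.11, -1.72 ± 0.11 and -1.21 ± 0.08 (-2.13, -2.43, -1.90 and -1.33 unmixed).

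**Figure D1:**
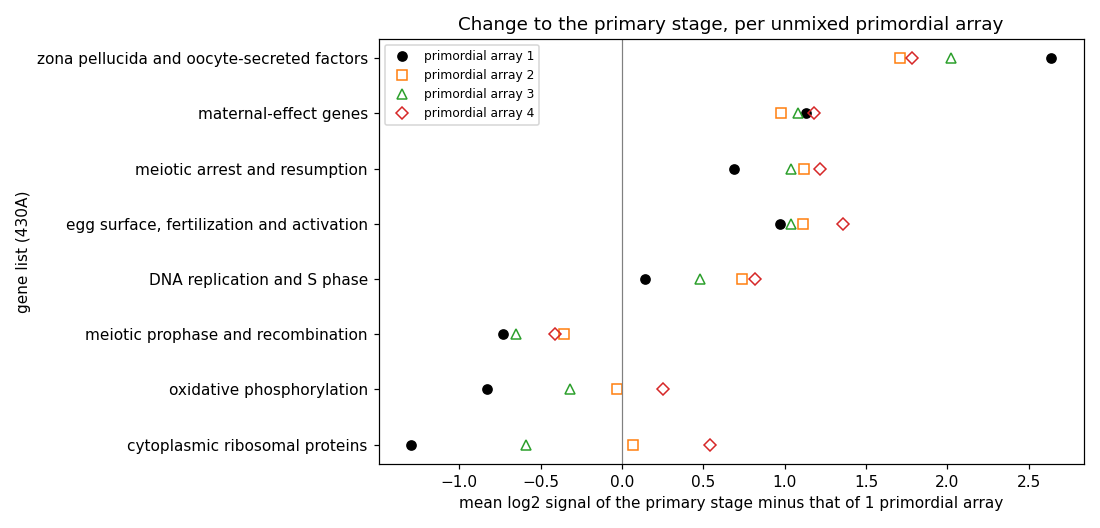
Mean log2 signal of 8 gene lists at the primary stage minus that of each unmixed primordial array (430A; x axis in log2 units, 1 symbol per array). Ribosomal protein genes lie between -1.30 and 0.54 and oxidative phosphorylation genes between -0.83 and 0.25, on both sides of 0, while zona pellucida and oocyte-secreted factors lie between 1.71 and 2.64.

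In all, 8945 of 15845 tested 430A probe sets changed between primordial and primary oocytes (4198 rose, 4747 fell), 3619 of them at least 2-fold (3980 unmixed), and 6058 of 19115 on 430B (2296 rose, 3762 fell). The unmixed values called 7878 on 430A and 4259 on 430B, of which 6966 and 3892 were called in the same direction as deposited. The share of rises among 430B calls was 37.9% here, 48.8% with quantile normalization and 62.2% with arrays scaled to the same median, which moved the median log2 change of all 430B probe sets from -0.23 to 0.05, so the balance of directions on 430B depended on the scaling. On 430A the same scaling moved the median log2 change from -0.08 to 0.06 and turned the balance, with 4951 rises and 3812 falls (56.5% rising against 46.9%). Among markers of other cell types, 2 of 18 granulosa cell markers rose and 5 fell (3 and 5 unmixed; camera adjusted p = 0.67, and 0.34 unmixed). Of 10 theca, stroma and fibroblast markers 0 rose and 3 fell (0 and 4 unmixed), with a mean change of -0.70 (-0.93 unmixed; adjusted p = 0.34, and 0.12 unmixed), and of 8 ovarian surface epithelium markers 4 rose and 2 fell (4 and 0 unmixed), with a mean change of 0.12 (0.55 unmixed; adjusted p = 0.8, and 0.49 unmixed).

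**Figure D2:**
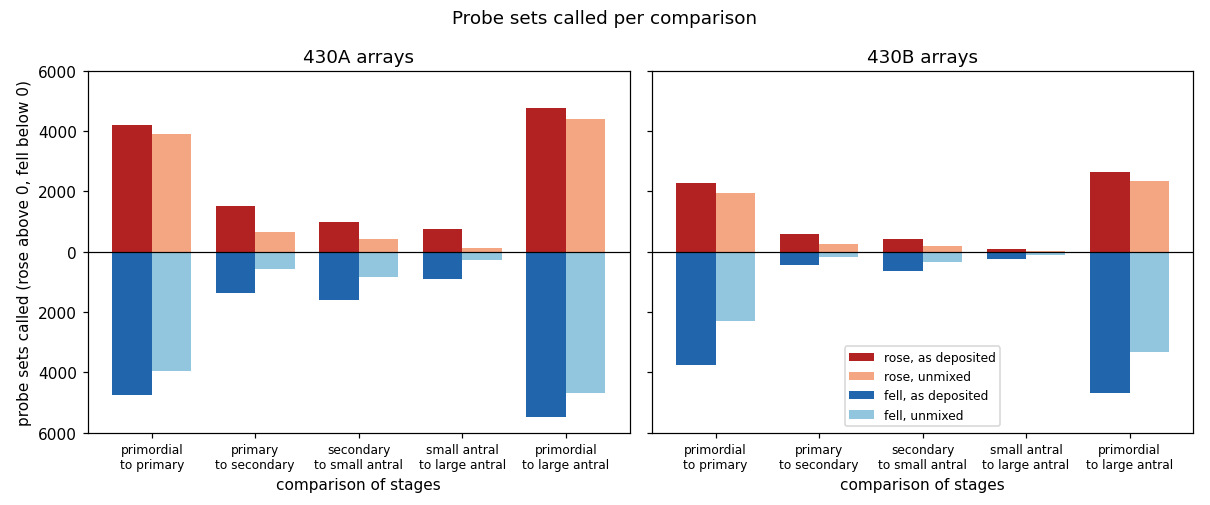
Number of probe sets called in each comparison of stages (limma, Benjamini-Hochberg adjusted p under 0.05), rises above 0 and falls below 0, for the deposited and the unmixed primordial values on each array type. The primordial to primary bars (4198 rises and 4747 falls on 430A) exceed those of each later transition.

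The primary to secondary transition, within the growing pool, moved fewer probe sets. The acute-phase gene Hp (haptoglobin) went from 18.1 to 449.1 in mean signal, a log2 change of 3.26 ± 0.16. The uridine phosphorylase gene Upp1 rose by 2.36 ± 0.13, Tctex1d1 by 2.27 ± 0.17, Gtf2ird1 by 2.16 ± 0.22, the endocytic adaptor gene Dab2 by 2.13 ± 0.15 and Lrrc4 by 2.11 ± 0.22. On 430B, Tex26 rose by 3.55 ± 0.27 and Fam162b by 3.08 ± 0.21. Maged1 fell from 1426.3 to 186.5, a log2 change of -2.75 ± 0.20, and Rimklb changed by -1.99 ± 0.32, Myot by -1.94 ± 0.13, C130026I21Rik by -1.76 ± 0.26, Bex1 by -1.72 ± 0.18 and the fatty acid oxidation gene Hadh by -1.67 ± 0.16. On 430B, Zfp618 changed by -2.44 ± 0.12 and Dpp9 by -2.35 ± 0.31. The adjusted p of these 16 genes lay at or below 1e-04.

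Sohlh1, Figla and Sycp3, which had fallen from primordial to primary, fell again. Sohlh1 changed by -1.62 ± 0.16, Figla by -0.90 ± 0.13, Sycp3 by -1.29 ± 0.16 and Kit by -0.64 ± 0.15 (a call lost with unmixed primordial values), while Bmp15 rose by 0.86 ± 0.19 and Dnmt3l by 0.77 ± 0.12. The levels of Zp1, Zp2, Zp3, Nlrp5, Lhx8, Nobox, Zar1, Gdf9, Dnmt1 and Dmc1 were not called as different, with log2 changes between -0.31 and 0.28 (adjusted p from 0.073 to 0.94). Gdf9 (0.27) and Dnmt1 (-0.31) passed the threshold in a fit without the primordial stage, Nlrp5 (-0.234) with quantile normalization and Nobox (0.278) with only the 2 stages compared. Oxidative phosphorylation was the gene list that passed: 15 of 88 members fell and 4 rose (15 and 5 adjusted over the list alone; 4 and 1 with unmixed primordial values), with a mean change of -0.11 (camera adjusted p = 0.0081, 0.042 with unmixed primordial values, and 0.76 as the adjusted p with an estimated correlation). Ndufa1 changed by -0.54 ± 0.08, Cyc1 by -0.69 ± 0.13, Ndufa5 by -0.56 ± 0.11 and Ndufb9 by -0.56 ± 0.13. Of 45 DNA replication genes 12 rose and 4 fell (14 and 5 adjusted over the list alone, camera adjusted p = 0.16). Among markers of other cell types, 2 of 8 ovarian surface epithelium markers rose and 0 fell, with a mean change of 0.54 (camera adjusted p = 0.13). For theca, stroma and fibroblasts 2 of 10 rose and 0 fell, with a mean change of 0.06, and for granulosa cells 1 of 18 rose and 0 fell.

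A total of 2887 probe sets changed on 430A (1503 rose, 1384 fell; 373 at least 2-fold) and 1024 on 430B (599 rose, 425 fell). In fits without the primordial stage the counts were 3067 and 1002, and in fits with the unmixed primordial values, whose larger spread enters the shared variance, they were 1226 and 423.

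From secondary to small antral follicles, falls outnumbered rises on both array types. The regucalcin gene Rgn went from 254.1 to 2432.4 in mean signal, a log2 change of 3.10 ± 0.24. The metalloprotease gene Mep1b rose by 2.56 ± 0.20, Trim31 by 2.55 ± 0.21, the neural adhesion gene Cntn6 by 2.44 ± 0.20, the antigen-presenting molecule gene Cd1d1 by 2.39 ± 0.25 and Bcl2l15 by 2.33 ± 0.23. On 430B, Mei4, of meiotic double-strand break formation, rose by 2.70 ± 0.22 and Pnma5 by 2.53 ± 0.12. Tmx1 changed by -2.42 ± 0.14, Shmt1, of one-carbon metabolism, by -2.39 ± 0.19, the hedgehog receptor gene Ptch1 by -2.36 ± 0.22, Sp4 by -2.29 ± 0.15, Scamp1 by -2.26 ± 0.11 and Riox1 by -2.24 ± 0.18. On 430B, Zbtb49 changed by -3.51 ± 0.33 and Eid2 by -2.55 ± 0.22. The adjusted p of these 16 genes lay at or below 3.3e-07.

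Sohlh1 (-1.19 ± 0.16), Figla (-0.74 ± 0.13), Sycp3 (-0.63 ± 0.16) and Zp1 (-0.38 ± 0.10) fell, the calls of Sohlh1 and Zp1 being lost with unmixed primordial values, and Dnmt3l rose by 0.71 ± 0.12. Gdf9, Zp2, Zp3, Nlrp5, Dnmt1, Nobox, Lhx8, Kit, Bmp15, Zar1 and Dmc1 were not called as different, with log2 changes between -0.37 and 0.62 (adjusted p from 0.066 to 0.89). Dmc1 passed the threshold without secondary replicate 3 (0.779) or small antral replicate 2 (0.759), Kit without secondary replicate 1 (-0.474) and Dnmt1 without the primordial stage (-0.367). No gene list passed the threshold by camera. Of 33 genes of meiotic arrest and resumption 5 rose and 0 fell (camera adjusted p = 0.32), of 18 granulosa cell markers 2 rose and 0 fell (adjusted p = 0.52), and of 22 piRNA and transposon silencing genes 2 rose and 6 fell (3 and 6 adjusted over the list alone; adjusted p = 0.52). The log2 ratio of 3' to 5' signal was 3.07 ± 0.08 in secondary and 2.86 ± 0.06 in small antral oocytes for Gapdh (exact permutation p = 0.0286, adjusted p = 0.0572), and 2.37 ± 0.09 and 2.88 ± 0.37 for Actb (exact p = 0.0571, adjusted p = 0.0856). On 430A 2577 probe sets changed (970 rose, 1607 fell; 504 at least 2-fold). On 430B 1063 changed (419 rose, 644 fell).

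On 430B the extraction notes of small antral replicates 2 to 4 state 60 oocytes from mice 12 days old, which are the secondary stage values. Their grouping here follows the titles. Without these 3 samples, 453 probe sets of 430B changed (109 rose, 344 fell), 314 of them among the 1063, and the change of Sohlh1 no longer passed the threshold at a log2 change of -0.885. In fits without the primordial stage the counts were 2754 and 982, and with unmixed primordial values they were 1268 and 526.

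The last transition, from small to large antral follicles, was the smallest, and zona pellucida and secreted factor transcripts were lower at its end. Of 8 such genes 5 fell and 0 rose (7 and 1 adjusted over the list alone; 1 and 0 with unmixed primordial values), with a mean change of -0.38 (camera adjusted p = 0.0014, and 0.3 as the adjusted p with an estimated correlation). Zp3 went from 22958.9 ± 2074.1 to 15569.5 ± 1729.7 (log2 change -0.56 ± 0.10), Gdf9 from 30274.4 ± 2403.7 to 20908.2 ± 1913.2 (-0.53 ± 0.10), Fgf8 changed by -0.55 ± 0.13, Zp2 by -0.39 ± 0.12 and Bmp15 by -0.60 ± 0.19. With quantile normalization the list's mean change was -0.149 and its call was lost, as were those of Zp2, Zp3, Gdf9 and Nlrp5, so these falls depended on the normalization. The highest deposited signal of a 430A array lay between 8754 and 11804 at the small antral stage and between 6649 and 7732 at the large antral stage. With unmixed primordial values the list kept its call (adjusted p = 0.005), while those of Gdf9, Fgf8, Zp2, Bmp15 and Nlrp5 were lost. Those of Zp2 and Bmp15 were also lost with no filter on low signals, without a variance trend, and without any of several single replicates (with log2 changes between -0.361 and -0.405 for Zp2 and between -0.496 and -0.633 for Bmp15). With an offset of 0 the calls of Fgf8 (-0.571) and Bmp15 (-0.606) were lost. The log2 ratio of 3' to 5' signal of the Gapdh control was 2.86 ± 0.06 in small antral and 2.37 ± 0.10 in large antral oocytes (exact permutation test, two-sided, p = 0.0286, adjusted p = 0.0572 over 6 tests), and that of Actb 2.88 ± 0.37 and 3.08 ± 0.75 (exact p = 0.8).

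Tcfl5 rose most on 430A, by 1.96 ± 0.22, followed by Zfp423 (1.70 ± 0.28), Nckipsd (1.48 ± 0.34), the peptide receptor gene Vipr2 (1.44 ± 0.32), Rnf10 (1.43 ± 0.32) and the imprinted gene Nap1l5 (1.43 ± 0.39). On 430B, Gm31679 rose by 1.98 ± 0.43 and Kif26a by 1.63 ± 0.40. The calls of Rnf10, Nap1l5 and Kif26a were lost with unmixed primordial values and with an offset of 0. Leaving out small antral replicate 1 or 2, or large antral replicate 2 or 3, ended the call of Nap1l5 (1.115 to 1.416), leaving out small antral replicate 4 or large antral replicate 4 that of Gm31679 (1.838 and 1.752), and leaving out any of 5 single replicates that of Kif26a (1.531 to 1.599). Those of Gm31679 and Kif26a were also lost without the small antral samples of conflicting protocol, and that of Kif26a without the primordial stage (1.627). Bhlhe40, a clock-related repressor gene, changed by -2.15 ± 0.26, the lactate dehydrogenase gene Ldhc by -1.93 ± 0.15, Esyt3 by -1.83 ± 0.20, the sulfate transporter gene Slc26a2 by -1.69 ± 0.15, the chromatin gene Hmga2 by -1.57 ± 0.30 and Appl1 by -1.47 ± 0.16. On 430B, Fam241a changed by -2.16 ± 0.28 and Gk5 by -2.03 ± 0.31, a call that was lost with only these 2 stages in the fit. The adjusted p of these 16 genes lay at or below 0.034.

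Nlrp5 fell by 0.39 on the log2 scale, and Kit rose by 0.50 ± 0.15 (adjusted p = 0.039) with another probe set going the opposite way. The call of Kit was lost with unmixed primordial values, with scaling to the same median, with no filter, without a variance trend and without any of 5 single replicates (0.406 to 0.518). Zp1, Dnmt1, Nobox, Lhx8, Figla, Sycp3, Dmc1, Dnmt3l, Zar1 and Sohlh1 were not called as different, with log2 changes between -0.36 and 0.24. Figla passed the threshold with array weights (-0.388) and without small antral replicate 3 (-0.459). Of 18 granulosa cell markers 3 rose and 0 fell (3 and 0 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.33). On 430A 1643 probe sets changed (744 rose, 899 fell; 169 at least 2-fold) and on 430B 358 (100 rose, 258 fell). The counts were 1041 without small antral replicate 1, 1050 without large antral replicate 2 and 1057 without large antral replicate 3 on 430A, and 229 without small antral replicate 4 and 218 without large antral replicate 1 on 430B. In fits without the primordial stage they were 1809 and 297, and with unmixed primordial values 395 and 110, with 32.9% and 10.9% of calls rising against 45.3% and 27.9% before. Without the small antral samples of conflicting protocol 313 probe sets of 430B changed, 60.7% of them rising, and 123 were among the 358.

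Across the whole span, from primordial to large antral follicles, Gm1070, Obox2 and other oocyte transcripts rose, while Sohlh1, Figla and Sycp3 fell. Obox2 rose by 7.21 ± 0.11 on the log2 scale (6.99 unmixed), to 21489.1 ± 1616.8. Cpa1 rose by 6.38 ± 0.21 (6.08 unmixed), Upp1 by 6.09 ± 0.13 (5.98 unmixed), Mettl7a2 by 5.29 ± 0.26 (5.27 unmixed), Rfpl4 by 5.23 ± 0.14 (5.22 unmixed) and the transcription factor gene Ehf by 5.01 ± 0.11 (4.98 unmixed). On 430B, Gm1070 rose by 8.06 ± 0.13 (7.99 unmixed) and Oog3 by 7.24 ± 0.29 (6.78 unmixed). Oxr1, an oxidation resistance gene, changed by -5.61 ± 0.12 (-5.89 unmixed), the translation inhibitor gene Eif4ebp1 by -5.25 ± 0.17 (-4.38 unmixed), Maged1 by -5.07 ± 0.20 (-4.37 unmixed), Wdr45b by -4.93 ± 0.21 (-4.90 unmixed), Ift27 by -4.91 ± 0.20 (-4.02 unmixed) and Rimklb by -4.67 ± 0.32 (-4.07 unmixed). On 430B, Neb changed by -5.51 ± 0.40 (-4.47 unmixed) and Sohlh1 by -5.24 ± 0.16 (-4.02 unmixed). The adjusted p of these 16 genes lay at or below 4.2e-11 as deposited and 1.5e-07 unmixed.

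**Figure D3:**
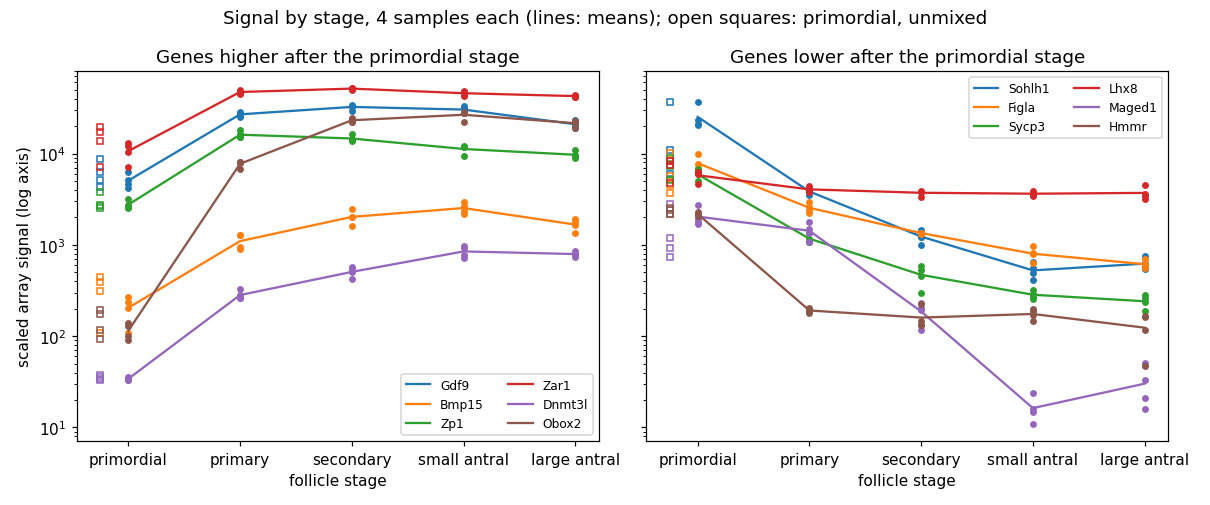
Scaled array signal (log axis) of 12 genes at the 5 follicle stages, with 4 samples per stage as filled circles, their means joined by lines, and the 4 unmixed primordial values as open squares to the left. Gdf9 is at 5052.5 in primordial and 26831 in primary oocytes, and Sycp3 goes from 5907 to 241.1 at the large antral stage.

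Sycp3 changed by -4.45 ± 0.16 (-4.68 unmixed) and Figla by -3.59 ± 0.13 (-3.09 unmixed), while Dnmt3l rose by 3.64 ± 0.12 (3.64 unmixed), Bmp15 by 2.89 ± 0.19 (2.44 unmixed), Gdf9 by 2.05 ± 0.10 (1.84 unmixed), Zar1 by 2.03 ± 0.13 (1.67 unmixed), Zp1 by 1.80 ± 0.10 (1.75 unmixed) and Nobox by 0.76 ± 0.12 (0.97 unmixed). Lhx8 changed by -0.64 ± 0.11 (-0.90 unmixed). Of 27 meiotic prophase genes 7 rose and 13 fell (7 and 16 adjusted over the list alone; 6 and 13 unmixed; camera adjusted p = 0.13), and of 16 oocyte transcription factor genes 9 rose and 6 fell (9 and 6 adjusted over the list alone; 7 and 6 unmixed; adjusted p = 0.52). Zp2 changed by -0.58 ± 0.12 (-0.96 unmixed) and Nlrp5 by -0.65 ± 0.09 (-0.87 unmixed), but with quantile normalization their changes were 0.09 and 0.003. The rises of Zp3 (0.43 ± 0.10, and 0.227 unmixed) and Dnmt1 (0.93 ± 0.16, and 0.469 unmixed) lost their calls unmixed, and the change of Kit went from -0.43 ± 0.15 to 0.092. The call of Kit was also lost with scaling to the same median (-0.238), without primordial replicate 1 (-0.302) and without large antral replicate 4 (-0.378). Zona pellucida and oocyte-secreted factor genes had 7 rises and 1 fall among 8 (6 and 1 unmixed), a mean change of 2.02 and a camera adjusted p of 0.003 (0.011 unmixed), with an adjusted p of 0.3 with an estimated correlation. Of 33 genes of meiotic arrest and resumption 23 rose and 3 fell (23 and 4 adjusted over the list alone; 23 and 3 unmixed), with a mean change of 1.10 and a camera adjusted p of 0.0012 (0.0012 unmixed), and an adjusted p of 0.22 with an estimated correlation. Mos rose by 4.68 ± 0.13 (4.90 unmixed), Bub1b by 4.03 ± 0.10 (4.32 unmixed), Aurka by 2.02 ± 0.12 (2.43 unmixed) and Map2k1 by 1.44 ± 0.08 (1.54 unmixed).

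Of 48 ribosomal protein genes 43 fell and 1 rose (43 and 1 adjusted over the list alone), against 21 and 1 unmixed. The mean change was -1.16 as deposited and -0.47 unmixed (camera adjusted p = 7.4e-11 and 0.0066), with an adjusted p of 0.4 with an estimated correlation. Rps20 (-1.96 ± 0.10; -2.18 unmixed), Rps28 (-1.79 ± 0.09; -1.94 unmixed), Rps2 (-1.32 ± 0.08; -1.28 unmixed) and Rpsa (-2.17 ± 0.14; -1.75 unmixed) were among them. Of 88 oxidative phosphorylation genes 60 fell and 6 rose (61 and 6 adjusted over the list alone), against 42 and 10 unmixed. The mean change was -0.82 as deposited and -0.43 unmixed (camera adjusted p = 3.2e-09 and 0.0012), with an adjusted p of 0.3 with an estimated correlation. Examples were Ndufa1 (-2.01 ± 0.08; -2.13 unmixed), Atp5g3 (-2.17 ± 0.09; -2.24 unmixed), Ndufa5 (-2.48 ± 0.11; -2.69 unmixed) and Ndufv2 (-1.93 ± 0.09; -2.03 unmixed). In the same deposited samples the 18S ribosomal RNA control probe set had a deposited signal of 6569.6 ± 1955.4 in primordial and 411.4 ± 109.7 in large antral oocytes (SD, n = 4). The log2 ratio of 3' to 5' signal for Actb was 2.18 ± 0.29 in the deposited primordial samples, with 1.77, 5.94, 3.03 and 6.24 in the 4 unmixed arrays, and 3.08 ± 0.75 in large antral oocytes, so the direction of its difference depended on the unmixing. For Gapdh it was 2.01 ± 0.50 in the deposited primordial samples and 2.37 ± 0.10 in large antral oocytes, and unmixing gave a negative 5' signal in 1 array. No test is given for these, since the deposited primordial samples are not independent and the control probe sets did not all follow the form of the other probe sets. In all, 10274 probe sets of 430A changed (4784 rose, 5490 fell; 5391 at least 2-fold, and 5459 unmixed) and 7342 of 430B (2640 rose, 4702 fell), against 9103 and 5654 unmixed. The share of rises among 430B calls was 36.0%, 49.2% with quantile normalization and 58.1% with arrays scaled to the same median, which moved the median log2 change from -0.25 to 0.06 on 430B and from -0.07 to 0.10 on 430A, where the share of rises went from 46.6% to 55.6%. Of 18 granulosa cell markers 7 rose and 4 fell (7 and 3 adjusted over the list alone; 8 and 4 unmixed; camera adjusted p = 0.8), and of 7 endothelial cell markers 5 rose and 0 fell (3 and 0 unmixed; adjusted p = 0.42). Of 8 ovarian surface epithelium markers 5 rose and 2 fell (5 and 1 unmixed), with a mean change of 0.65 (1.23 unmixed; camera adjusted p = 0.67, and 0.36 unmixed). Of 10 theca, stroma and fibroblast markers 2 rose and 4 fell (2 and 4 unmixed), with a mean change of -0.83 (-1.07 unmixed; adjusted p = 0.52, and 0.26 unmixed).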

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

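All tests of explanations in this part were chosen after the results they bear on had been seen. In 334 groups of 4 samples, 14 had 1 sample far from the other 3, and chance gives such a sample in about 1 in 20 groups of independent samples. The deposited primordial replicates 2 to 4 had the form of means with replicate 1, so that rate does not hold for the primordial groups. Among single genes these were Bex3 in primordial replicate 1 (scaled signal 1792.3, others 1440.9 to 1490.7), Ndufa12 in primordial replicate 1 (5388.3, others 6734.5 to 7012.4), Ehf in primordial replicate 4 (50, others 42.6 to 43.3) and in large antral replicate 4 (2211.7, others 2503.2 to 2543.2), and Obox2 in primary replicate 1 (6765.7, others 7916.9 to 8147.6). Kit in primary replicate 2 stood at 5070.9, Zp3 in primary replicate 4 at 21904, Cyc1 in secondary replicate 1 at 1557.2, Lhx8 in secondary replicate 3 at 3323.2, Figla in secondary replicate 4 at 1309.6 and Rimklb in secondary replicate 3 at 21.1. Zp1 in small antral replicate 1 stood at 9379.8 and Vipr2 in small antral replicate 4 at 76.3. On 430B, 72% of probe sets of primordial replicate 1 reached a signal of 100, against 77.4% to 77.9% of the other primordial replicates.

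The deposited primordial replicates 2 to 4 were not so low that doubling them gave less than replicate 1 at any of the 22526 probe sets of 430A and 22411 of 430B in this count. Separate arrays that happen to be alike would carry values on the grid of the other arrays, but at least 49.4% of values of these columns lay off it. Columns that are means of replicate 1 and another array are a candidate explanation, for which the share of values off the grid is separate evidence. The count of 0 negative values of the doubled value minus replicate 1, against at least 1085 in pairs of other stages, is the pattern itself and adds no test. Among 100 probe sets of 430A off the 0.1 grid at other stages 10 were negative for replicate 3, and among 64 controls 1 and 2 for replicates 3 and 4, so these columns are not such means throughout. How the averaging came about, and whether the authors intended it, was not tested.

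The fall of ribosomal protein and oxidative phosphorylation transcripts from primordial to primary oocytes may come largely from the extra weight of replicate 1. Over unmixed arrays 2 to 4 the mean change was 0.01 ± 0.57 (SD, n = 3) for ribosomal protein genes and -0.03 ± 0.29 for oxidative phosphorylation genes, against -1.30 and -0.83 for replicate 1, which does not show which array is the unusual one. RNA of granulosa or stroma cells in replicate 1 is argued against by the 430A markers. The log2 mean of 13 granulosa cell markers was lower there than in the unmixed arrays 2 to 4 (a difference of -0.56, SD of those arrays 0.18). That of 7 theca, stroma and fibroblast markers was also lower (-0.74, SD 0.19). Cdkn1c (555 ± 153.8) and Ptch1 (785.8 ± 147.6) had the highest deposited primordial signals of the 2 lists on 430A. The granulosa cell marker Foxl2, measured on 430B and outside these means, stood at 1580 ± 162.8. Gja1 (37.1 ± 7.7) and Hsd17b1 (21.5 ± 22.6) were the lowest tested granulosa cell markers, while Inha (277.7 ± 41.8) and Irx3 (230.9 ± 33.7) were higher. The change of the stroma list to the primary stage was -0.38 against replicate 1 and -1.12 ± 0.19 against arrays 2 to 4. For the granulosa list it was 0.11 and -0.45 ± 0.18. RNA of such cells in arrays 2 to 4 is therefore not argued against. Oocytes express an unknown number of these markers, which limits the argument. A difference in RNA integrity stays open: the unmixed Actb log2 ratio of 3' to 5' signal was higher in arrays 2 to 4 than in replicate 1 by 3.3 (SD of the 3 arrays 1.77), highest in arrays 2 and 4 that showed no fall of ribosomal protein genes, but control probe sets did not all follow the averaging and the arrays are few. A higher share of these transcripts in primordial oocytes stays open, because the unmixed arrays spread too widely (exact permutation p = 0.4857 for ribosomal protein and 0.3429 for oxidative phosphorylation genes, 4 against 4 arrays).

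Small antral replicates 2 to 4 on 430B carry a protocol of the secondary stage. If they held secondary oocyte RNA, their difference from the secondary samples would not follow the small antral change measured on 430A. Across 93 genes, which are not independent replicates, called at least 2-fold on 430A and also measured on 430B, their correlations with that change were 0.49, 0.47 and 0.45, against 0.39 for small antral replicate 1 and between -0.12 and 0.15 for secondary samples. Secondary RNA in these samples is argued against, and a copied protocol text was not tested.

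For each of the 6 counts of the later transitions, 1 of the 35 splits of the 8 arrays into 4 and 4, the real one, called as many. That is the smallest share that 35 splits can give. It argues against chance in the grouping for each count, but not against mouse age or pool size, which changed with the stage. The highest counts of the other splits were 3 against 2887, 301 against 2577 and 4 against 1643 on 430A, in the order of the transitions, and 7 against 1024, 47 against 1063 and 7 against 358 on 430B. Every other split mixes the stages within a group, so the stage difference widens the spread and lowers these counts. The size of the gap therefore adds nothing to the rank of 1 in 35. From the primordial stage 1 of 35 splits, the real one, also called as many with the deposited values, but these columns share replicate 1, so their splits decide nothing. Their highest other counts were 2 against 8945 and 0 against 10274 on 430A, and 2 against 6058 and 1 against 7342 on 430B. With unmixed values 1 of 35 splits, the real one, called as many for each of those counts, with the same limits. The highest of the other splits were 4047 against 7878 (primordial to primary) and 3356 against 9103 (primordial to large antral) on 430A, and 342 against 4259 and 267 against 5654 on 430B.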

How the results depend on the processing

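The unmixed primordial values and the fits without the primordial stage were chosen after the data were seen; the other settings were fixed before. The 10 counts stayed within 1.5 times under an offset of 0 or 64, signals as deposited, quantile normalization, both other filters, array weights and the replicate block, and the 6 counts of later transitions did so without the primordial stage. Unmixed values gave 1226, 1268 and 395 probe sets for the 3 later transitions on 430A and 423, 526 and 110 on 430B, since their larger primordial spread enters the shared variance; the 4 counts that involve the primordial stage stayed within 1.5 times. On 430B eBayes without trend gave 658 from primary to secondary and 163 from small to large antral, the last of which also moved to 225 with scaling to the median and 112 with only the 2 stages compared, for causes that were not tested. Without the samples of conflicting protocol 453 changed from secondary to small antral on 430B, with 1 small antral sample left, which is assumed to vary like the other groups.

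With each replicate left out, counts on 430A ranged from 8446 to 8769 (primordial to primary), 2322 to 2685 (primary to secondary), 2182 to 2420 (secondary to small antral), 1041 to 1615 (small to large antral) and 9823 to 10044 (primordial to large antral), and on 430B from 5062 to 5639, 749 to 950, 839 to 990, 218 to 447 and 6438 to 6918.

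Quantile normalization turned the log2 changes of Zp2 and Nlrp5 to 0.295 and 0.346 from primordial to primary and to 0.09 and 0.003 from primordial to large antral. The cause of these turns was not tested. Unmixing turned the change of Kit from primordial to large antral to 0.092. The 4 unmixed primordial signals of Kit were 5748.6, 2231.1, 3183.6 and 2194.9, so replicate 1 set much of its deposited level. All 12 list calls were lost with an estimated correlation, and that of zona pellucida genes from small to large antral also with quantile normalization (-0.149); the 12 lists kept direction and call with scaling to the median and with unmixed values.

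Replicate numbers did not pair the samples strongly, as at most 2 of 4 same-numbered pairs in any comparison had deviations correlated over 0.1, and none over 0.13. On 430A, 6 of 8 samples from primordial to large antral and 5 of 8 from primary to secondary correlated best with their own number. Weak pairing is therefore not excluded. The replicate block gave 8909, 2907, 2589, 1659 and 10244 probe sets on 430A and 5985, 991, 1038, 337 and 7289 on 430B. Precision was lower on 430B, with a median standard error of 0.34 against 0.17 on 430A and 34% of simulated log2 changes of 1 from secondary to small antral recovered against 76%; the cause was not tested.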

Other observations

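Few probe sets were highest in a single later stage. On 430A 3004 of 15845 were higher in primordial oocytes than in each other stage (2321 unmixed), against 53 in primary, 4 in secondary, 0 in small antral and 39 in large antral oocytes (14, 1, 0 and 4 with unmixed values). Highest in primordial oocytes were Psat1 (510.8 ± 131.2, SD, n = 4; 352.3 ± 260.9 unmixed; next stage 15), Retreg1 (2531.9 ± 657.5, 3430.4 ± 1401.8 unmixed, next stage 195), Bex3 (1552 ± 161.7, 1377.7 ± 306.4 unmixed, next stage 132.7), the spindle-associated gene Hmmr (2177 ± 84.8, 2317.2 ± 178 unmixed, next stage 191.1) and Psma8, a germ cell proteasome subunit gene (535.4 ± 51.2, 487.3 ± 95.8 unmixed, next stage 29.3). Primary oocytes had the highest levels of Ran (2530.8 ± 108.3, next stage 1094.4), the imprinted adaptor gene Grb10 (1618.1 ± 154.9, next stage 730.4), Cbr3 (748.6 ± 103), Pla1a (2593.8 ± 118) and Mrvi1 (161.9 ± 33.1). The genes highest in secondary oocytes were Gm9222, C1galt1c1, Kti12 and Zfp334. In large antral oocytes Zfp423 (222.9 ± 35.3), Tmem229b (235.5 ± 40.3), Gja1 (143.5 ± 20), Slc9b1 (638.9 ± 105.1) and the cyclin gene Ccnd2 (684.1 ± 71.3, next stage 315.6) were highest. With unmixed values the calls of Grb10, Cbr3, Mrvi1, C1galt1c1, Kti12, Zfp334, Tmem229b, Gja1 and Slc9b1 as highest in 1 stage were lost (adjusted p from 0.1 to 1).

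Gja1, a gap junction gene, is also 1 of the 18 granulosa cell markers listed before the data were examined. Its log2 change from small to large antral was 1.17 ± 0.24 and that of another marker, Hsd17b1, 1.02 ± 0.32, while Foxl2, the marker with the highest signal, stood at 1811.6 and 1787.2. The mean signal of Inha went from 434.9 to 568.1 and that of Esr2 from 280.1 to 391. In this transition 3 of the 18 markers were called as rises and 0 as falls (camera adjusted p = 0.33). Hsd17b1, Foxl2, Inha and Esr2 were chosen after their values were seen.

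Array types gave different directions for part of the genes they share. Of 2782 genes with tested probe sets on both, 622 were called by both from primordial to primary and 419 of these (67.4%) in the same direction, with a correlation of log2 changes of 0.22 across genes, which are not independent replicates. From primary to secondary 55 of 58 shared calls had the same direction (94.8%) from secondary to small antral 64 of 75 (85.3%), from small to large antral 13 of 14 (92.9%) and from primordial to large antral 612 of 867 (70.6%). The correlations of these were 0.23, 0.2, 0.06 and 0.31 across genes. With unmixed primordial values 278 of 397 (70%) did from primordial to primary, and with scaling to the same median 412 of 568 (72.5%). The probe sets of a gene on 430B match other parts of its transcripts, and no explanation was tested.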
